A study of Drosophila melanogaster with 3 samples.

How the data were processed

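ChIP-seq with an anti-GFP antibody was done on embryos of a transgenic fly line with GFP fused to the C-terminal end of Insv, in 3 biological replicates of whole embryos of mixed sex, aged 0 to 24 h. Per the labels, chromatin was sonicated to fragments of 200 to 800 bp. All 3 replicates were treated as a single group, and no second condition exists.

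The deposited region lists are in narrowPeak format, 5 on each of the genome builds dm6 and dm3: a relaxed list for each replicate, a relaxed list for the replicates pooled, and the list of peaks that passed the authors' IDR test. Per the file headers, each relaxed list was called by the authors on the alignments and a control alignment. The signal value of each deposited region is the peak caller's own score, of unstated scale, and was used in all tests only as a rank within a single list; the map of the E(spl) complex alone draws its log10. The authors' significance column holds −log10 q-values, used here only to count regions with a q-value below 0.05. The deposited summit position is another column, an offset in bp from the region start. The peak caller, the aligner, the IDR threshold and the read numbers are not given in the sources used here, so no depth per sample can be stated. The relaxed lists held 30000 regions each on dm6, a count that looks like a limit, and the 4753 IDR peaks were the 4753 regions of the pooled list with the highest score.

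Positions are on dm6 and count from 1. Genes, TSSs and sequence came from the Ensembl release 115 annotation of BDGP 6.54 and the matching genome sequence, limited to the major chromosome arms, with 13945 protein-coding genes and 23998 TSSs of any gene. No coordinates were converted between builds. Older symbols in the gene lists were matched to current ones. Intervals of shares are Wilson 95% intervals, which cover counting error only.

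Comparisons, gene lists, motifs, the rule for named genes and most alternatives were fixed before the data were examined. For replicate overlap, the 4753 strongest regions of each replicate were used. Low-ranked regions, 14491 in number, came from the weaker 50% of the pooled relaxed list without overlap with an IDR peak. Promoter peaks had a summit within 500 bp of a TSS. Motifs were sought on both strands within 50 bp of the summit, against 4467 low-ranked windows drawn to match the promoter share, and sequences of 8 bases were tested where at least 10 windows held them. A gene was bound if a summit lay within 500 bp of any of its TSSs, so neighbours can share a peak. For head-to-head pairs, a single TSS per gene was used, with at most 1000 bp between the starts. Each comparison used Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the motifs, the sequences of 8 bases or the lists, and a threshold of 0.05. Peak strength was compared by a permutation test of medians with 100000 resamples. Regions and genes are not replicates, so each comparison was repeated on the lists of each replicate, and means and SDs over the 3 are given.

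The named genes are those nearest to the 20 strongest IDR peaks, insv, up to 8 bound members of the Notch pathway, E(spl) and Bearded, Hox, insulator and proneural lists in order of score, their unbound members where fewer than 10, and up to 4 bound members of each other list.

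The alternatives were other windows, backgrounds, overlap rules, motif forms and TSS distances, the dm3 lists, the stronger 50% of the IDR peaks (2376), 10000 random gene lists matched on the number of TSSs, and leaving out each replicate in turn. Leaving out a replicate kept the IDR peaks whose summits lay among the strongest regions of both other replicates. The IDR list itself still drew on all 3 replicates, so this is a stricter filter and not a removal of data. The alternative that keeps the strongest summit of each group of overlapping peaks, and the 25 bp window for motifs of other proteins and promoters, were chosen after seeing the data.

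The methods were tested on simulated data. Planted sequences of 8 bases were found in 5 of 50 cases when added to 0.5% of windows, in 44 at 1% and in 50 at 2%, and with nothing planted 0 of 29153 were called. Gene lists of 20 or more genes with odds raised 5-fold were found in 93.0% of cases and those raised 2-fold in 36.6%, while 13 of 1200 unchanged lists were called. Rank shifts of 20 points were found in 100 of 100 simulations, shifts of 5 points in 20, and 6 of 100 without a shift were called.

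Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Boundary elements of the bithorax complex are not annotated in the reference used, so no peak was assigned to them.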

Results

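Insensitive (Insv) is a fly nuclear protein with a BEN domain, a fold that binds DNA, and acts as a corepressor in the Notch pathway. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured where Insv fused to green fluorescent protein (GFP) at its C-terminal end lay on chromatin in whole Drosophila melanogaster embryos of mixed sex, aged 0 to 24 h. An anti-GFP antibody was used on 3 biological replicates from a single transgenic line. The samples form a single group with no second condition, so regions of the genome were compared with each other. Read numbers were not given in the sources used here, so the depth is unknown and precision rests on the 3 replicates. Each replicate's list on the dm6 genome build held 30000 regions, of which 8416 in replicate 1, 13955 in replicate 2 and 12195 in replicate 3 had a q-value below 0.05.

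The first question was where the reproducible peaks lay and how well the replicates shared them. The list that passed the authors' test of reproducibility (irreproducible discovery rate, IDR) held 4753 peaks at 4022 separate loci, with a median length of 510 bp. The strongest peak by the authors' signal score lay at Dpm3, a subunit of dolichol-phosphate mannose synthase, on 3R from 13402583 to 13403924, with its summit 186 bp from the transcription start site (TSS). The next peaks lay at Prosap, a postsynaptic scaffold (2R, 14140279 to 14141730), and in an intron at PH4alphaEFB, which hydroxylates collagen (3R, 30466545 to 30467936). Among the 20 strongest, the nearest genes also included the Cullin adaptor gene rdx, the proton pump gene VhaAC45, the ubiquitin-activating enzyme gene Uba1, the phosphoglycerate mutase gene Pglym78, and the cochaperone genes Sgt1 and Dpit47. The remaining nearest genes were CG43138, Cph, CG10602, tun, the glycosyltransferase gene Ugt36A1, CG4935, CG3529 and l(3)L1231, together with 3 developmental regulators. These 3 were the proneural gene l(1)sc, with a summit 2078 bp away at X 407643, the pair-rule gene ftz, with a summit 6642 bp away at 3R 6870966, and the Hox gene Scr, with a summit 4529 bp away at 3R 6854510. In the replicate lists, each of these 20 peaks had a mean signal percentile of 99.9 or higher.

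Of the IDR summits, 86.3% ± 3.10 (SD, n = 3) lay inside the 4753 strongest regions of a replicate, at 83.7% for replicate 1, 89.7% for replicate 2 and 85.5% for replicate 3. All 3 replicates held 3226 of the peaks (67.9%) among their strongest regions, and 18 peaks were in none of these sets. The IDR peaks are the top of the pooled list, which draws on each replicate, so part of this overlap is set in advance. Between pairs of replicates, 79.1% of the strongest summits were shared by replicates 1 and 2, 74.3% by 1 and 3, and 82.6% by 2 and 3.

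The insv gene itself carried a strong peak. Its summit lay at 2L 2577288, within a peak from 2576230 to 2578228, 291 bp from the insv TSS and 399 bp from that of the neighbouring gene Elba2, which encodes another BEN-domain protein. This peak ranked 57 of 4753, with a percentile of 99.8 ± 0.0830 (SD, n = 3) in the replicates, and had no Insv site within 50 bp of its summit.

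The next comparison asked which parts of genes the peaks occupied. Insv peaks lay mostly at promoters: 3119 of 4753 summits (65.6%, Wilson 95% interval 64.3 to 67.0%) were within 500 bp of a TSS. Among 14491 low-ranked regions, taken from the weaker 50% of the pooled list, the share was 20.2%. In the pooled list 12516 of 30000 regions had a q-value below 0.05, so the low-ranked regions include many without significant signal. Introns held 21.6% of the summits, intergenic DNA 9.45% and exons 3.35%, against 43.2%, 18.5% and 18.1% of the low-ranked regions. The median distance to a TSS was 200 bp for peaks and 1882 bp for low-ranked regions. In the replicates the promoter share was 65.0% ± 1.34 (SD, n = 3) for the strongest regions and 20.6% ± 0.928 for the low-ranked ones, a difference far above the replicate spread. The odds ratio was 7.53 (95% interval 7.00 to 8.09), and the p of Fisher's exact test, two-sided, was too small for double precision. It was 13.3 against random positions and 4.79 against all listed regions outside the IDR peaks.

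Promoters shared by a pair of genes on opposite strands carried peaks far more often than others. There were 2436 such head-to-head pairs, with TSSs at most 1000 bp apart, and 1957 of their 4650 genes (42.1%) had a summit within 500 bp of their outermost TSS, against 1227 of 9295 other genes (13.2%). Examples are the peak shared by insv and Elba2 and that shared by Dref, a transcription factor gene, and RpL13 on 2L, with its summit at 9967341. The odds ratio was 4.78 (95% interval 4.39 to 5.2; Fisher's exact test, two-sided, p = 2.21e-306). A single peak between the starts can count for both genes of a pair. The genes are therefore not independent, the p is too small, and part of the excess can arise from this sharing alone. In the replicates the shares were 40.1% ± 3.78 and 12.8% ± 0.488 (SD, n = 3).

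The sequence under the summits was then compared with the sequences that Insv and its relatives are known to bind. The Insv core palindrome CCAATTGG lay within 50 bp of 165 of 4753 IDR summits (3.47%), against 12 of 4467 low-ranked summits (0.269%) drawn to the same promoter share. The degenerate Insv site TCYAATHRGAA lay at 214 summits (4.50%) against 4 (0.09%). The Elba site CCAATAAG, bound by the BEN-domain Elba complex, lay at 87 summits (1.83%) against 6. For the core palindrome the odds ratio was 13.4 (95% interval 7.42 to 24.0; Fisher's exact test, two-sided, p = 2.77e-34, Benjamini-Hochberg adjusted p = 2.91e-33 over 21 motifs). In the replicates the core was at 3.51% ± 0.175 of the strongest summits and 0.257% ± 0.115 of the low-ranked ones (SD, n = 3), with odds ratios from 10.3 to 30.4. The odds ratio was 52.6 (19.5 to 142) for the degenerate site and 13.9 (6.06 to 31.7) for the Elba site, with adjusted p of 3.18e-55 and 7.36e-18 in the same exact tests. In the replicates the odds ratio of the degenerate site was 42.5 ± 20.1 (SD, n = 3), and that of the Elba site was lower than in the IDR list, at 6.36 ± 0.353. None of 5 reordered palindromes of the same bases passed the test within 50 bp, but AACCGGTT did within 100 bp (odds ratio 2.14, adjusted p = 0.0332, exact test). With low-ranked windows also matched on GC content, the odds ratio of the core palindrome was 7.78 and that of the degenerate site 25.6. Over all alternative windows, backgrounds and peak sets, the odds ratio ranged from 7.78 to 19.5 for the core, from 25.6 to 114 for the degenerate site and from 7.07 to 24.0 for the Elba site, each past the threshold.

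**Figure D1:**
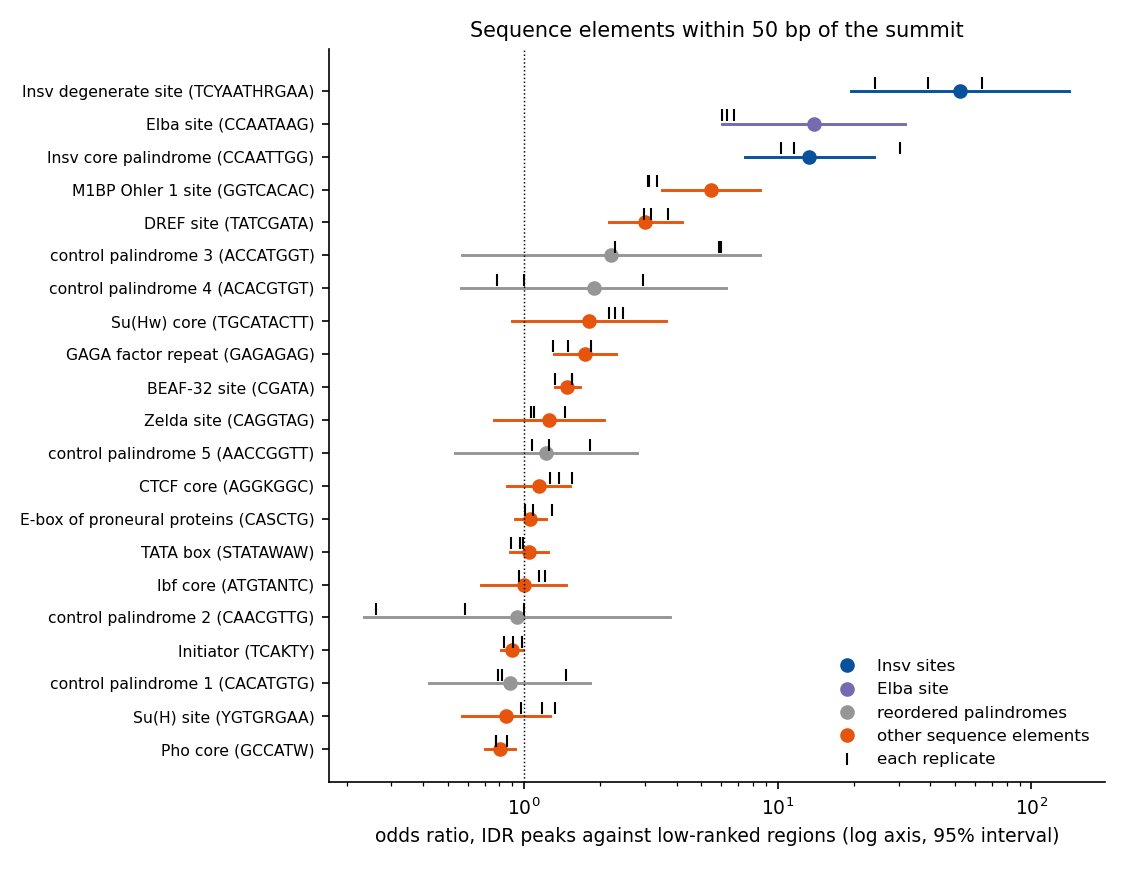
Odds ratio (log axis) of each motif within 50 bp of the summit in IDR peaks against low-ranked regions, with 95% intervals, and ticks for the 3 replicates. The 3 BEN-domain sites, which can share matches, stand farthest from 1, and the control palindromes have intervals that reach 1.

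Sequences of other promoter and boundary proteins were also more frequent under the peaks. The low-ranked windows were matched on the share within 500 bp of a TSS, not on closer distance or promoter activity. Differences between the promoters compared can therefore contribute to these results. The M1BP site GGTCACAC lay at 2.76% of summits against 0.515% (odds ratio 5.48, adjusted p = 7.36e-18), the DREF site TATCGATA at 3.09% against 1.05% (3.00, adjusted p = 1.2e-11), and the BEAF-32 site at 19.5% against 14.1% (1.48, adjusted p = 9.27e-12), each by Fisher's exact test and past the threshold in 3 of 3 replicates. The replicate odds ratios were 3.18 ± 0.152 for M1BP, lower than in the IDR list, 3.28 ± 0.368 for DREF and 1.47 ± 0.127 for BEAF-32 (SD, n = 3). The BEAF-32 sequence, CGATA, lies within the DREF site, so every DREF match also counts for BEAF-32. The results of DREF and BEAF-32 are therefore not independent. The GAGA factor repeat was more frequent at 2.88% against 1.68% (1.74, adjusted p = 0.000367, past the threshold in 2 of 3 replicates), and the Pho core less frequent at 8.86% against 10.8% (0.805, adjusted p = 0.00594, in 2 of 3), by the same exact test. Sites of Su(H), the DNA-binding protein of the Notch pathway, did not pass, with an odds ratio of 0.848 (95% interval 0.570 to 1.26, adjusted p = 0.572 in Fisher's exact test), nor did those of CTCF, Su(Hw), Zelda, proneural proteins or Ibf, the TATA box or the Initiator. Of these, CTCF, the E-box of proneural proteins and the Initiator each passed in 1 of 3 replicates. Against flanks 500 bp to each side, GAGA (adjusted p = 0.23) and Pho (0.617) lost their calls, Su(Hw) gained one (odds ratio 3.55, adjusted p = 0.000741), and DREF and M1BP reached 7.75 and 12.8, in exact tests. Without replicate 3 the GAGA adjusted p was 0.0913 (odds ratio 1.41), and without replicate 2 that of Pho was 0.122 (0.852), while without replicate 1 the Initiator passed (adjusted p = 0.0448, odds ratio 0.876), again by exact tests. With the GC-matched windows, the proneural E-box (odds ratio 1.29, adjusted p = 0.0161), the Initiator (0.868, 0.0433) and the TATA box (0.749, 0.0134, turned from 1.04) passed the exact test as well. GAGA and Pho did not pass the exact test in the stronger 50% of peaks (odds ratios 1.44 and 0.891, adjusted p = 0.165 and 0.476) or within 25 bp of the summit (1.53 and 0.869, adjusted p = 0.109 and 0.278), a window chosen for these motifs after the data were seen.

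Among all sequences of 8 bases, 28356 were tested and 135 were enriched, with 21 depleted. The lowest p belonged to AATTGGAA, at 5.07% of summits (odds ratio 5.91), followed by CCAATTGG and CAATTGGA. CCAATCAG, at 2.38% of summits (odds ratio 9.87), and the Elba and M1BP sites were also among the first 7.

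Insv sites were concentrated in the strongest peaks. The core or the degenerate site lay at 148 of the 476 strongest summits (31.1%), at 14.9% of the next 10% of the list and at 1.26% of the weakest 10%. The replicates gave 31.4% ± 0.993, 13.6% ± 1.2 and 1.82% ± 0.121 (SD, n = 3). Among the 20 strongest peaks, such sites lay at Prosap, PH4alphaEFB, Sgt1, CG10602 and Ugt36A1, and the Elba site at l(1)sc, Pglym78 and Cph. The median rank percentile was 89.8 for the 165 peaks with the core and 48.6 for the others, a difference of 41.2 points (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give). The difference was 41.3, 40.1 and 40.3 points in replicates 1, 2 and 3, and 41.2 among promoter peaks alone. Over the whole list, 305 peaks (6.42%) had either site within 50 bp, and 646 (13.6%) within 250 bp, against 0.455% and 1.90% of low-ranked regions. Core sites were also frequent 150 to 300 bp from the summit toward lower coordinates, with 116 there against 41 at the same distance on the other side. These are counts for each summit, so a site near several summits counts at each. Of the 116, 87 lay beside weaker summits of groups of overlapping peaks.

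**Figure D2:**
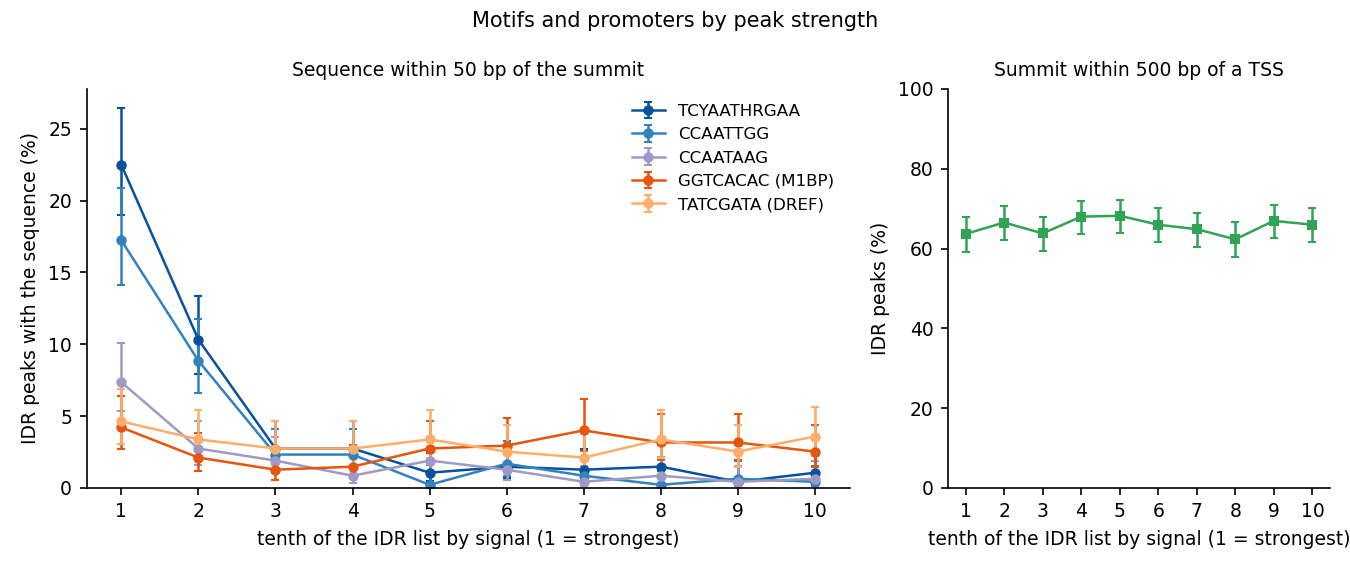
Percent of IDR peaks with a sequence within 50 bp of the summit, and percent at promoters, by consecutive 10% of the list from strongest (1) to weakest (10), with Wilson 95% intervals as bars. The degenerate site was at 22.5% and the core at 17.2% of the strongest 10%, while the promoter share lay between 62.3% and 68.2%.

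**Figure D3:**
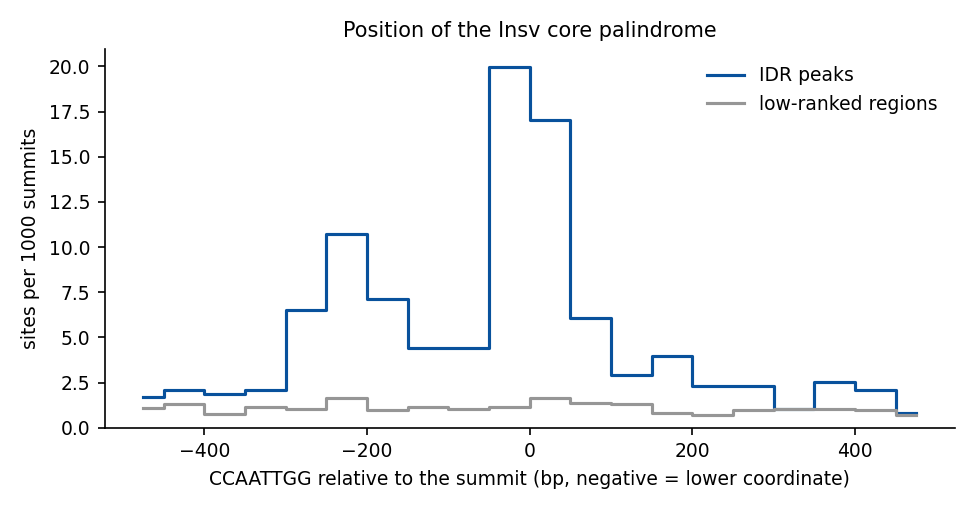
Core sites per 1000 summits by position relative to the summit, in bp, for IDR peaks and low-ranked regions. Sites were counted for each summit, so a site near several summits counts at each. Of 486 such counts within 500 bp of IDR summits, 176 (36.2%) lay within 50 bp.

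Which genes carried Insv peaks at their promoters was tested with 21 gene lists. Peaks lay within 500 bp of a TSS of 3456 of 13945 protein-coding genes (24.8%). Ribosomal protein genes had the highest share, 70 of 86 (81.4%), with the strongest peaks at RpL26 (rank 27), RpS26 (110), RpL8 (303, with a core site) and RpL34b (580). Their odds ratio was 13.5 (95% interval 7.85 to 23.3; Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 5.7e-27), and the replicates gave 79.5% ± 2.42 (SD, n = 3). Among the 70 bound genes, 1, RpL8, had an Insv site within 50 bp of a promoter summit. Genes for odorant and gustatory receptors (0 of 119, adjusted p = 2.27e-14) and for cuticle proteins (0 of 100, adjusted p = 4.88e-12) had no IDR peak within 500 bp, by the same exact test. With a 1000 bp window 3 receptor genes and 1 cuticle gene were bound, and with the nearest TSS within 5000 bp 3 and 2. In replicate 1 alone, 1 receptor gene was bound. In all, 9 lists were bound more often than other genes and 2 less often, and 10 of these 11 passed in each replicate.

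Genes of the E(spl) and Bearded complexes, most of which encode bHLH repressors or Bearded family proteins that respond to Notch signalling, were bound in 12 of 16 cases (75%). The strongest of these peaks lay at Brd (rank 164, percentile 99.4 ± 0.164, SD, n = 3), followed by E(spl)m2-BFM, E(spl)malpha-BFM, E(spl)m3-HLH, E(spl)m4-BFM, E(spl)m8-HLH, E(spl)mbeta-HLH and E(spl)m5-HLH, at ranks from 653 to 2451. None of the 12 genes had an Insv site within 50 bp of its strongest promoter summit. BobA, E(spl)m6-BFM, E(spl)mgamma-HLH and Tom had no promoter peak. Many genes of the list lie side by side in the E(spl) complex, so they are not independent. Neither the exact test nor the simulated lists allow for this. The odds ratio was 9.13 (95% interval 2.94 to 28.3; Fisher's exact test, adjusted p = 0.00012). It was 2.33 in replicate 1 alone, where 43.8% were bound (adjusted p = 0.251 in the exact test), against 75% in replicate 2 and 68.8% in replicate 3. It was 7.07 without replicate 1 (adjusted p = 0.000496), 3.52 without replicate 2 (adjusted p = 0.0302) and 3.11 without replicate 3 (adjusted p = 0.0512, exact tests). The lower values come from peaks that also had to be among the strongest of replicate 1. For the stronger 50% of peaks the odds ratio was 5.24. When each peak went to the gene with the nearest TSS within 5000 bp, all 16 genes were bound (adjusted p = 2.47e-10, exact test), so no finite odds ratio can be given. The E(spl) complex, from 3R 25996621 to 26050911, held 24 peaks or 44.2 per 100 kb, against 3.55 per 100 kb over the genome; it was chosen for this density count after the data were seen.

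**Figure D4:**
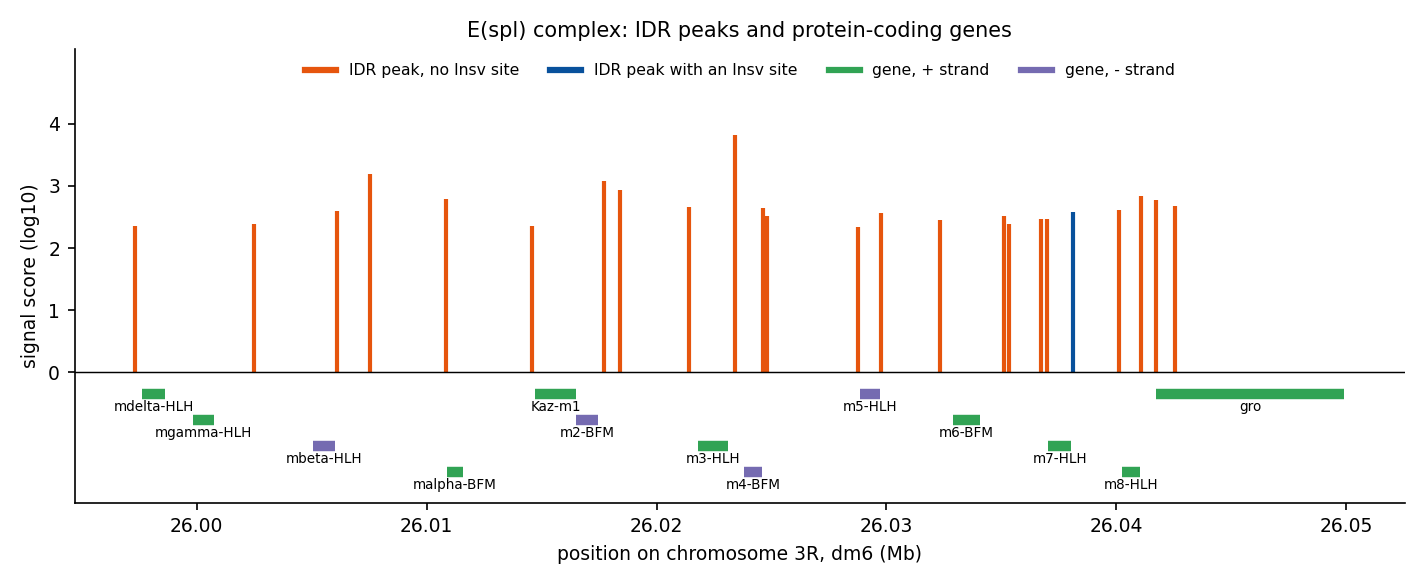
IDR peaks over the E(spl) complex on 3R (position in Mb), each bar at the summit and as high as the log10 of its signal score, coloured by the presence of an Insv site, above the protein-coding genes coloured by strand. The strongest of the 24 peaks lay at 26023390, between E(spl)m3-HLH and E(spl)m4-BFM.

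Other genes of the Notch pathway were bound in 11 of 21 cases (odds ratio 3.35, 95% interval 1.42 to 7.89; Fisher's exact test, adjusted p = 0.0178), and the share was 58.7% ± 9.91 in the replicates (SD, n = 3). Beside insv, they included the glycosyltransferase fng (rank 256, both Insv sites), numb and neur, which act in asymmetric division, the corepressor gro, Nedd4, the gamma-secretase subunit aph-1 and the receptor gene N (rank 1554). Against random lists matched on the number of TSSs, the adjusted p of the permutation test was 0.0618. Insulator and BEN-domain protein genes were bound in 13 of 20 cases (odds ratio 5.65, 95% interval 2.25 to 14.2; Fisher's exact test, adjusted p = 0.000385). They included insv and Elba2, which share a peak, and Cp190, Chro, su(Hw), Trl, Dref and M1BP at ranks from 709 to 1238; Clamp, Elba1, Elba3, Ibf1, Ibf2, ZIPIC and dwg had none. With the nearest TSS within 5000 bp, 9 of 20 were bound (2.96, adjusted p = 0.0428, exact test).

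Genes of signalling pathways were bound in 20 of 31 cases (odds ratio 5.54, Fisher's exact test, adjusted p = 1.73e-05), among them spi (rank 255), tkv (447), wg (701) and hh (1369), with an odds ratio of 3.30 without replicate 3 (adjusted p = 0.00696) and 3.21 for the stronger 50% of peaks, and of 10.4 with the nearest TSS within 5000 bp (adjusted p = 4.48e-09, exact tests). Cell cycle genes followed with 15 of 24 (5.08, adjusted p = 0.000259 in the exact test), among them CycE (rank 72), dup, Mcm2 and E2f1, and an odds ratio of 3.37 for the stronger 50% of peaks. Housekeeping lists also passed the exact test: aminoacyl-tRNA synthetases with 19 of 32 (4.45, adjusted p = 0.00012), among them AlaRS-m, TyrRS, GluRS-m and ValRS; mitochondrial ribosomal proteins with 34 of 73 (2.66, adjusted p = 0.000166), among them mRpL13, mRpS21, mRpL40 and mRpL41; and proteasome subunits with 14 of 32 (2.37, adjusted p = 0.0415), among them Rpt4, Rpt3, Rpn7 and Prosalpha5. The calls of these 3 lists ended when each peak went to the gene with the nearest TSS within 5000 bp, with odds ratios of 1.64 (adjusted p = 0.278), 0.932 (0.932) and 1.01 (1) in exact tests. With the stronger 50% of peaks the synthetases and the proteasome both had an odds ratio of 2.25 (adjusted p = 0.103, exact test), and the proteasome 0.0501 without replicate 3 (odds ratio 2.40) and 0.0517 against matched random lists.

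**Figure D5:**
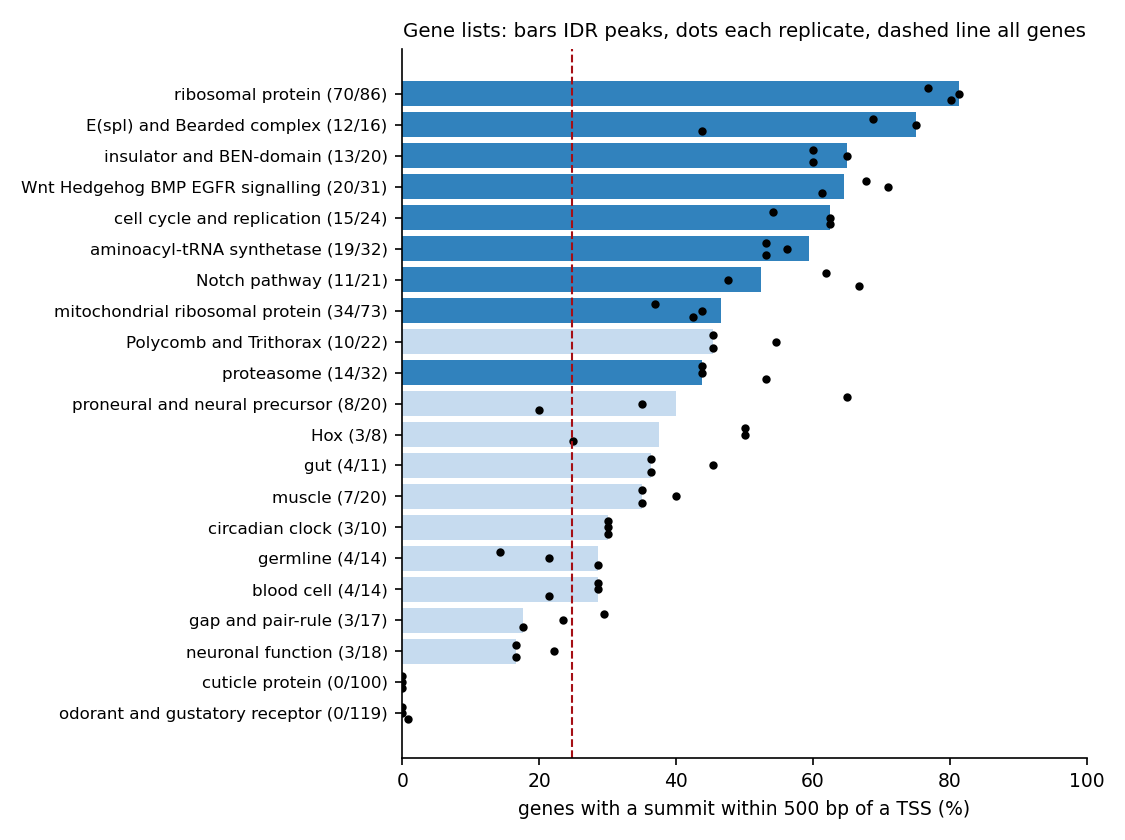
Percent of the genes of each list with a summit within 500 bp of a TSS, as bars for IDR peaks (dark where the list passed the test with a share above that of other genes) and dots for the 3 replicates, with a dashed line at 24.8% for all genes. Ribosomal protein genes stand highest at 81.4%, and the receptor and cuticle lists had no bound gene by the IDR peaks.

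Lists of the Polycomb and Trithorax groups, proneural, Hox, gap and pair-rule, neuronal, muscle, germline, blood cell, gut and clock genes did not pass. Polycomb and Trithorax genes were bound in 10 of 22 cases (odds ratio 2.53, Fisher's exact test, adjusted p = 0.0759), with Su(z)2, brm, ph-p and E(z) strongest, and passed without replicate 1 (2.94, adjusted p = 0.0427), with a 1000 bp window (2.64, 0.0496), with the nearest TSS within 5000 bp (3.62, 0.00679) and with the stronger 50% of peaks (3.15, 0.0369). This list also passed in 2 of 3 replicates. Proneural and neural precursor genes were bound in 8 of 20 cases (2.03, adjusted p = 0.199 in the exact test), namely brat (rank 83, with a core site), insc, phyl, sna, pros, dpn, esg and l(1)sc, but in 4, 7 and 13 of 20 by the lists of replicates 1, 2 and 3. They passed in 1 of 3 replicates, replicate 3, with an odds ratio of 6.60. Their odds ratio was 2.28 without replicate 1, 1.13 without replicate 2 and 0.998 without replicate 3. The lower values come from peaks that also had to be among the strongest of replicate 1. Of the Hox genes, Antp, Abd-B and Scr had promoter peaks and Dfd, Ubx, abd-A, lab and pb had none (1.82, adjusted p = 0.586 in the exact test). With the nearest TSS within 5000 bp, 6 of 8 were bound (10.8, adjusted p = 0.00508, exact test), and the gut (6.32, 0.00679) and muscle (2.96, 0.0428) lists passed too. Bound members of the remaining lists included opa (rank 198, both Insv sites), bcd and slp1; elav, fne and Csp; Mef2, tin, Tm1 and sls; bgcn, gcl, nanos and spn-E; ush, lz, gcm and crq; fkh, mex1, bowl and Hnf4; and sgg, dco and Pdp1.

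Over the chromosomes, the X held 866 of 4753 peaks (18.2%), against 20.3% of low-ranked regions (odds ratio 0.875, 95% interval 0.805 to 0.952; Fisher's exact test, two-sided, p = 0.0019). The replicates did not share a direction, with odds ratios of 1.13, 0.915 and 0.840 in replicates 1, 2 and 3, so this difference did not hold in every replicate. Against random positions it was 1.01 (p = 0.779 in the exact test) and for the stronger 50% of peaks 0.948 (p = 0.349). It kept its call on dm3 (0.802, p = 5.74e-08, exact test), and leaving out each replicate in turn gave 0.902 to 0.903 (p from 0.0274 to 0.0365 in exact tests). Chromosome 4 carried 26 peaks, and no IDR peak lay outside the major arms in dm6. On the older dm3 build the IDR list held 5326 peaks at 4482 loci.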

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

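The test of replicate numbers for peaks without a site, its limit to the weaker 80% of the list, and the 50% bound on shares used below were chosen after the results were seen, as was the pattern of sites to the left of summits. The design has a single group, so no biological explanation was tested for the patterns weighed here.

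On the dm3 build, which the comparisons did not use, 5 IDR peaks lay outside the major arms: 2 on 2RHet, 2 on Uextra and 1 on XHet. Their best rank percentiles in that list were 62.0, 10.2 and 25.1, and they stand out only because signal appeared in sequence left out of the comparisons.

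Ribosomal protein promoters carried peaks in 70 of 86 cases. More TSSs per gene are argued against as the cause, since the share of 81.4% lay above the upper end of the 95% range of matched random lists (39.5%). Exact matches to the Insv sites up to 250 bp from the summit cannot account for most of these peaks: 3 of 70 (4.29%, Wilson upper limit 11.9%) had an Insv site within 250 bp, against 1.30% of low-ranked promoter regions (Fisher's exact test, p = 0.0690). Open or heavily transcribed promoters caught without an Insv site are a candidate explanation: the odds ratio was 0.829 (95% interval 0.115 to 5.98) for peaks with a site, resting on 1 bound gene, and 14.0 for peaks without. Neither openness nor transcription was measured here and a GFP-only library was not used here, so this stays open.

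Most reproducible peaks, 4448 of 4753, had no exact match to the core or the degenerate Insv site within 50 bp of the summit. Within 250 bp, 646 of the 4753 (13.6%) had one. Sequences close to these sites, such as CCAATCAG (odds ratio 9.87), were also enriched, and weaker matches were not weighed here. That the peaks without a site are side summits of a stronger peak with one is argued against for most, since 3.42% lay within 1000 bp of such a peak. Peaks without a site were in all replicates' strongest regions less often, at 66.2% against 92.5%, and over the weaker 80% of the list the difference was −14.8 points (95% interval −24.1 to −5.40), which would have favoured poor replication. Among peaks of like signal rank it was −0.366 (−2.47 to 1.74) over the whole list, and −1.44 (−8.41 to 5.53) without the strongest 20%. Poor replication of peaks without a site stays open, since these intervals reach both sides of 0. The IDR peaks compared were also the top of the pooled list by score, which itself draws on all replicates. Binding through partners or open chromatin was not tested.

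Core sites formed a separate group 150 to 300 bp to the left of summits, with 116 on the left and 41 on the right over all IDR peaks (exact binomial test, p = 1.73e-09). Sites were counted for each summit, so a site near several summits counts at each. Among the strongest summit of each group of overlapping peaks the counts were 29 and 31 (exact p = 0.897), a ratio of 0.935, which argues against a further group of sites beside strong summits. Weaker summits called to the right of a stronger summit are a candidate explanation: 684 of 731 weaker summits (93.6%) lay to the right, at a median gap of 206 bp. These weaker summits had 87 core sites on the left and 10 on the right (exact binomial test, p = 1.79e-16), so the excess lay with them. Why the caller placed them on that side stays open, since its settings are not given in the sources used here.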

How the results depend on the processing

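The alternative that keeps the strongest summit of each group of overlapping peaks, and the 25 bp window for motifs of other proteins and promoters, were chosen after seeing the data; all other alternatives were planned. Of the main results under alternatives, 69 values kept their direction and side of the threshold or stayed within the limits set, 4 moved, 1 reversed and 1 weakened. The overlap with replicates, 86.3% as reported, was 76.6% with 50% reciprocal overlap, 97.8% with the doubled number of regions and 98.4% for the stronger 50% of peaks, whose number is 2376 by construction; the cause was not tested for the overlap. The X chromosome odds ratio was 1.01 against random positions and 0.948 for the stronger 50% of peaks, and the cause was not tested. The list of mitochondrial ribosomal proteins had an odds ratio of 0.932 with the nearest TSS within 5000 bp, and the cause was not tested. Among the other lists, 152 values kept their call, 7 gained and 8 lost one; among motifs of other proteins and promoters and control palindromes these numbers were 148, 5 and 8. The TATA box reversed, with an odds ratio of 0.749 with GC-matched windows, and the cause was not tested. With the strongest summit of each group, the promoter odds ratio was 7.35, that of the core site 13.7 and that of head-to-head pairs 4.67. No paired analysis was possible because the samples form a single group. Unknown read numbers limit what weak regions can show, and the capped lists hide regions below the limit.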

Other observations

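The bound tested on shares of sites in the E(spl) list and the choice of the gene complexes described here came after the results were seen; the remaining tests were planned.

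The Hox complexes held several of the strongest peaks. The bithorax complex, from 3R 16655623 to 16973236, which controls the identity of posterior segments, carried 25 peaks, or 7.87 per 100 kb, against 3.55 over the genome. Its strongest peak ranked 21, with a summit at 16882835 in an intron, 13458 bp from the TSS of MSAmiP, and those at 16719796, with a degenerate site and 14630 bp from the TSS of Ubx, and 16919103, in an intron 15139 bp from that of Abd-B, ranked 39 and 40. The peak at 16719796 was within 500 bp of a TSS of a gene other than Ubx. In all, 4 of the 25 lay within 500 bp of a TSS. A core site lay at the peak with its summit at 16898575, which ranked 67. The Antennapedia complex, from 3R 6660427 to 7000228, carried 20 peaks, or 5.89 per 100 kb, and its strongest, ranked 16, lay between ftz and Antp, while that ranked 18 lay between Scr and ftz. The achaete-scute complex on X, which holds proneural genes, carried 3 peaks, or 3.15 per 100 kb, of which the strongest ranked 6.

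A hypothesis for the strong peak at insv was extra copies of the locus from the tagged transgene, which could raise the background around it. The number of listed regions within 20 kb of the insv TSS was 16, against a median of 12 over genes, at percentile 64.7. This count takes no account of the height of the regions, which were called against a control alignment in a list that looks capped. Extra copies need not change the count, so the test cannot decide the question.

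Another hypothesis was that Insv sites may drive the excess of peaks at head-to-head promoters. The odds ratio was 2.45 (95% interval 1.80 to 3.34) for peaks with an Insv site and 4.81 for peaks without, so the test argues against it for exact matches within 50 bp.

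For the E(spl) and Bearded genes, binding through Insv sites was a possible explanation. None of the 12 strongest promoter peaks had such a site within 50 bp of its summit (Wilson upper limit 24.2%), against 176 of 3444 other bound genes (5.11%; Fisher's exact test, p = 1). Exact matches within 50 bp are therefore unlikely to account for most of the peaks. Sites farther from the summit and weaker matches were not tested for this list.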
